A study of Brassica napus with 6 samples.

How the data were processed

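Roots of 4-week-old oilseed rape were sampled from 3 control and 3 GSH-treated replicates. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA. The probe identifiers belong to an Arabidopsis array, so rape transcripts were measured through probes of a related species. Sequence differences between the species could lower or mix the signals of family members.

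The authors deposited one table of log2-like values from 5.09 to 12.9, and these were used as deposited. Their background correction, summary method, normalization and log base are not given in the sources used here. R 2.7.2 is named in the submitters' processing notes. The unit was taken as log2 from the range of the values. Array medians lay within 0.1 of each other, the condition set for using the table without further normalization. The standard deviation of a probe over the 6 arrays had a median of 0.724 millionths of a unit and differed 1315-fold between its 1st and 99th percentiles. A separate scale factor for each probe leaves Welch's test of that probe unaffected. It does affect fold changes, the rank product, and limma's moderated test, which shares variance between probes. Depth in the sense of counts does not apply to arrays.

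Of 22810 probes, 64 array control probes were left out and 22746 were tested. The platform annotation paired 13513 of these with 1 gene and 503 with several, and 8730 were unnamed here. None was named from a probe with several genes. The named probes covered 13350 genes, and 11798 of these carry a locus identifier as their name. The rape gene table supplied as a reference shared no identifiers with the annotation and was not used.

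Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, estimated prior degrees of freedom 0.83), with Benjamini-Hochberg adjustment over 22746 probes and a threshold of 0.05. No filter on dim probes was used. Gene lists were tested with limma camera, two-sided, with a preset correlation of 0.01, on the probe of each gene with the highest mean. Before the data were examined, 32 lists were fixed, covering sulfur, glutathione, metals, nutrients, hormones, stress and root or leaf cell types. Of their 539 genes, 59 were measured, in 25 lists, and 6 lists had 3 or more measured genes. Every list with at least 1 measured gene was tested, since no minimum had been set. A further 8 lists were drawn up after seeing the data. Fixed lists were adjusted among themselves and added lists over all 33. Because 2 list symbols stood for other genes in the annotation, they were not matched, and 4 list genes were matched under another symbol.

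Named genes followed a rule fixed beforehand. It took the 10 largest rises and falls among called probes with 1 gene and groups that do not overlap. Where a direction had fewer than 10 calls, the smallest unadjusted p under the same conditions filled the places. It added 18 sulfur, glutathione and metal genes, and up to 4 members with the smallest p of each list described. No probe was called by limma on the deposited scale, so all places went by unadjusted limma p. Members of the added lists were chosen after their values were seen.

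Alternatives fixed beforehand were quantile normalization, median-centred arrays, brighter probes only, the replicate number as a block, leaving out each array, trended and robust variance, array weights, other thresholds, Welch's test, the rank product over 9 pairs of arrays with 100 shuffles, camera with an estimated correlation, fry and the mean of all probes of a gene. Another alternative, added after seeing the data, rescaled each probe by the root of order 4 of its SD over its cubed range-to-SD ratio. The pseudocount alternatives applied to linear values only and were not run.

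The steps were tested on simulated data for this comparison with 22746 probes, 200 of them shifted by 2, 4 or 8 noise SDs. With noise of the size seen in each probe, limma recovered 0%, 2.99% and 15.2% of these and called 3 unchanged probes. The rank product recovered 5.97%, 4.48% and 19.7% and called 160 unchanged probes, and limma after rescaling recovered 4.48%, 4.48% and 25.8% and called 51. With equal noise whose deviations were then scaled by the cubed range, limma recovered 0%, 4.48% and 40.9% and called 0 unchanged probes. The rank product then recovered 23.9%, 95.5% and 100%, calling 51 unchanged probes, and limma after rescaling 11.9%, 92.5% and 100%, calling 8. In a simulation of the list test over 13350 genes, a list of 100 genes shifted by 1 noise SD had a camera p of 1.93e-21. Of 100 unshifted lists, 1 had a camera p under 0.05. All simulated noise was independent between probes and between genes. These simulations therefore leave out any variation that genes share on the real arrays, and do not test the preset correlation of camera.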

Results

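Root RNA of oilseed rape (Brassica napus) was hybridised to 6 single-colour arrays. In 3 of them the plants had received reduced glutathione (GSH, the tripeptide thiol) on their leaves for 4 days. The other 3 came from untreated control plants. GSH was brushed on at 100 mM, 50 µL for each of 3 expanded leaves. The labels call the controls untreated and give them no dose, volume or treated leaves. An effect of GSH on the roots therefore cannot be told apart from one of brushing a solution on the leaves. The labels call the 3 arrays of each group biological replicates. The number of arrays limits the precision of every value below.

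The arrays resembled each other to an unusual degree. Over all 22810 probes every array had the same median of 5.84, lower quartile of 5.67 and upper quartile of 6.06 on the deposited log scale. The lowest correlation between any pair of arrays fell short of 1 by only 1.52e-08. A probe typically ranged over 1.91 millionths of a unit across the 6 arrays, and the widest range was 6386 millionths. The largest difference between group means was 0.0037 of a unit, too small to be read as a log2 ratio of RNA amounts. Differences are therefore given in millionths of a unit of the deposited scale, with the standard error of the fit, and are not fold changes. The log base and the way in which the spread was reduced are not given in the sources used here, so sizes cannot be compared between probes. A direction can be read only relative to the level each array was given in the deposited table. Centring the arrays on their medians added the same 0.598 millionths to every difference. Neighbouring probe means lay a median of 34.5 millionths apart, far more than the 1.91 over which a probe typically ranged. An array median therefore probably followed the few probes of middle rank, so centring does not test the level of a whole array. The 8 of 51 named genes that turned sign with centring did so by these 0.598 millionths alone, which says nothing about those genes singly.

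Single genes were not separated from the spread between arrays at the threshold set beforehand. By limma, 0 of 22746 probes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.062. On simulated data limma recovered 15.2% of shifts of 8 noise SDs with noise of the size seen in each probe. It recovered 40.9% with the scaled noise, so the count of 0 does not exclude changed genes. At an unadjusted limma p under 0.05 there were 1535 probes, 713 higher and 822 lower after foliar GSH. A split that mixed the groups gave more, 1719, so this count is not tied to the treatment. That split set control replicates 1 and 3 with foliar GSH replicate 3. With each probe scaled to the same spread, the first principal component held 25.5% of the variance. It separated the same 3 arrays from the rest, and so did not follow the treatment. Welch's test per probe gave 1012 at that level and 0 after adjustment. The rank product, which uses the size of the differences, called 137 probes higher and 281 lower, but on simulated data with unequal noise it called 160 unchanged probes. Sizes cannot be compared between probes here, so its calls can favour probes with a wide spread. The 3 GSH arrays lay all above the controls at 1281 probes and all below at 1307, together 11.4% of probes where chance gives 10%. Centring each array on its median turned the unadjusted split to 1008 higher and 413 lower. This arose because array medians differed by up to 1.65 millionths, about as much as single probes did. As the medians probably follow few probes, neither split shows a prevailing direction.

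Genes encoding cytosolic ribosomal proteins stood lower as a group in the roots of GSH-treated plants. Of 133 measured genes, 123 had a lower mean after GSH, with a median moderated t of -3.11. The list was drawn up after the lowest genes had been seen, so its direction is not independent evidence. Camera with its preset correlation gave an adjusted p of 4.02e-50, over the fixed and added lists together. With an estimated correlation the adjusted p was 6.91e-04, and fry gave an adjusted p of 0.0204. By limma no member passed the threshold over all probes, and 63 passed when adjusted over the list alone. The rank product, with the false calls noted above, called 68 members lower. At 84 of the 133 genes all GSH arrays lay below all controls, and at 1 gene all lay above. The median t was -3.13 with each array centred on its median, a setting that does not test the level of a whole array. Quantile normalization left 15 of the genes varying and ended the call, with a median t of -1.07 and a camera adjusted p of 0.607. The other members kept their rank and so were set to the same value on every array, so this setting cannot test them.

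**Figure D1:**
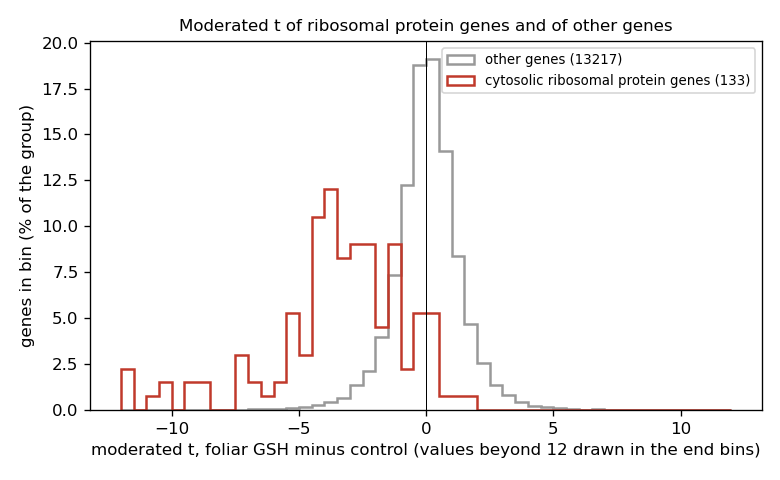
Distribution of the moderated t for foliar GSH minus control, as the percentage of genes per bin, for 133 cytosolic ribosomal protein genes and for all other named genes. The ribosomal protein genes have a median of -3.11 and lie mostly to the left of 0.

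Ribosomal protein genes made up 5 of the 10 lower genes with the smallest unadjusted limma p. The list was drawn up after the lowest genes were seen, so this is not further evidence for it. AT2G47610, a ribosomal protein of the large subunit, differed by -12.6 millionths (SE 0.636, limma adjusted p = 0.062). AT2G17360, of the small subunit, differed by -19.4 millionths (SE 1.22, limma adjusted p = 0.106). The acidic ribosomal protein gene AT5G57290 differed by -124 millionths (SE 10.8, limma adjusted p = 0.191). AT5G22440 differed by -68.2 millionths and AT1G36240 by -3.10 millionths, both genes of large-subunit proteins. Outside the ribosome, the beta-tubulin gene TUB7 differed by -16.1 millionths (SE 1.32), and AT3G23940, a dihydroxyacid dehydratase of branched-chain amino acid synthesis, by -25.2 millionths (SE 2.38). AT5G45920, AT5G19370 and AT5G15550 differed by -5.21, -3.76 and -6.39 millionths. Among probes above the median signal, tested alone, AT2G47610 and AT5G45920 passed with limma adjusted p of 0.0372 and 0.0487. None of the 10 passed by limma over all probes, while the rank product called 6, AT2G47610, AT2G17360, AT5G57290, AT5G22440, TUB7 and AT3G23940.

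The 10 higher genes with the smallest unadjusted p shared no list. BGAL16, a beta-galactosidase, differed by 9.23 millionths (SE 1.18, limma adjusted p = 0.337). KEU, a Sec1-type protein needed for cytokinesis, differed by 4.58 millionths (SE 0.449, limma adjusted p = 0.214). AT4G01150, a thylakoid membrane protein, differed by 4.65 millionths (SE 0.635). AT4G21450 had the smallest unadjusted p of the 10 and a difference of 2.92 millionths (SE 0.24, limma adjusted p = 0.191). AT3G43660 and AT2G32190 differed by 5.56 and 5.58 millionths. The AT2G32190 probe had a mean signal of 5.57, under the array lower quartile of 5.67. AT1G73120 differed by 3.302 millionths, and AT5G63130, AT2G19400 and AT1G63200 by 1.68, 1.62 and 1.55 millionths. None of these 10 passed over all probes by limma or by the rank product.

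**Figure D2:**
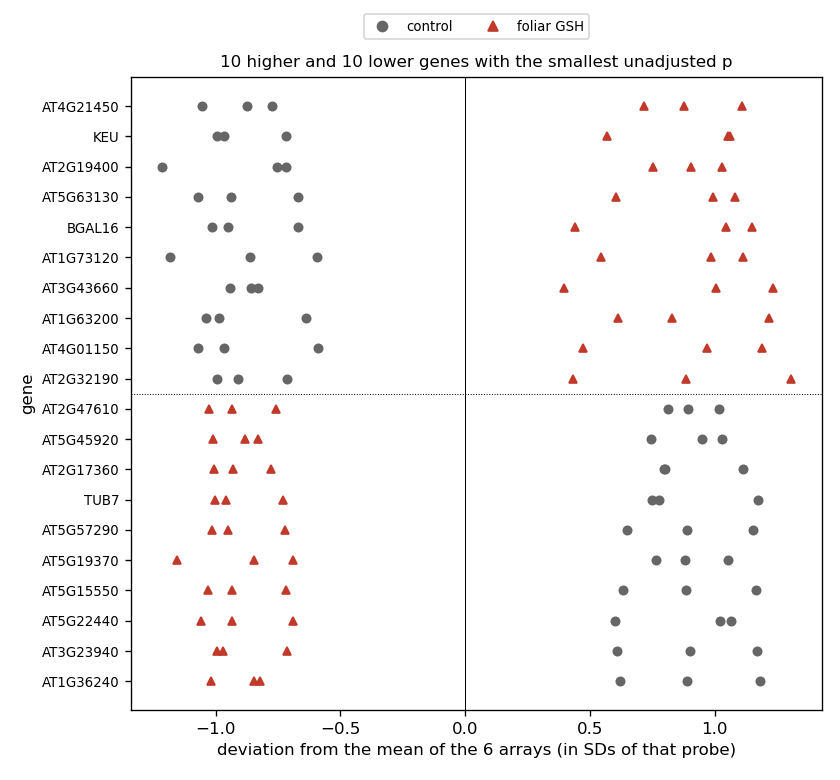
Values of the 10 higher and 10 lower genes on each array, as the deviation from the mean of the 6 arrays in units of the SD of that probe. Circles are the 3 control arrays and triangles the 3 GSH arrays. All 20 genes were selected for groups that do not overlap, and none passed the adjusted threshold by limma.

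Sulfur and glutathione genes fixed beforehand gave no call as lists, and with few members measured this does not exclude a shift. Of the 18 genes that were always to be reported, among them the root sulfate transporters, APR1 to APR3, GSH1, GSH2 and PCS1, 0 could be matched to a probe paired with 1 gene. In the sulfate assimilation list 3 of 24 genes were measured, and camera gave an adjusted p of 0.991. Its ATP sulfurylase gene APS4 differed by 29.9 millionths (SE 9.25, limma adjusted p = 0.647) with all GSH arrays above all controls. APS3 differed by -5.41 millionths (SE 8.31). The sulfite reductase gene SIR differed by -0.961 millionths (SE 0.543), with all GSH arrays below all controls. The median t of the list was -0.65 while its mean was 0.27 and camera placed it upward. The sulfur deficiency genes AT1G04770 and BGLU28 differed by -0.339 millionths (SE 0.322) and -0.208 millionths (SE 0.198), and both signs turned with median-centred arrays. The BGLU28 probe had a mean signal of 5.64, under the array lower quartile of 5.67. Whether such dim probes report expression was not tested. The glutathione reductase gene GR1 differed by 0.0137 millionths (SE 0.259). Of 37 glutathione S-transferase genes, 11 of the tau class were measured, 7 higher and 4 lower (camera adjusted p = 0.776). GSTU20 differed by 1.97 millionths (SE 1.36), GSTU25 by 0.358 (SE 0.271), GSTU18 by 0.775 (SE 0.896) and GSTU15 by -4.63 (SE 3.78). The GSTU15 probe, with a mean signal of 5.65, was also under the lower quartile. Without single arrays GSTU20 ran from 1.09 to 3.46 and GSTU15 from -8.65 to -1.88.

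Metal lists gave no call either. In the zinc and cadmium transport list 3 of 41 genes were measured (camera adjusted p = 0.776). The transporter gene ZIP9 differed by 1.86 millionths (SE 0.658), ZIP6 by -0.757 (SE 1.09) and the zinc-response regulator bZIP19 by -0.14 (SE 0.287), whose sign turned with centring. The median t of that list was -0.49, while its mean was 0.55. In the iron deficiency list 5 of 21 genes were measured, 3 higher and 2 lower (camera adjusted p = 0.515). Its member with the smallest unadjusted p was AT3G13610, the hydroxylase F6'H1 of coumarin synthesis, at 115 millionths (SE 35.7, limma adjusted p = 0.652), with all GSH arrays above all controls. AT3G12900, the scopoletin hydroxylase of the same pathway, differed by 1.75 millionths (SE 0.657). BHLH101 and PYE differed by -0.58 (SE 0.561) and 0.213 millionths (SE 0.444), and the sign of BHLH101 turned with centring. The BHLH101 probe was dim, with a mean signal of 5.54 under the array lower quartile of 5.67. The metallothionein gene MT1C, the only measured member of the ferritin and metallothionein list, differed by 399 millionths (SE 120, limma adjusted p = 0.64).

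Hormone lists and tissue markers were also without a call. In the abscisic acid list LTI30, COR15A and COR47 differed by 0.411 (SE 0.461), 0.223 (SE 0.502) and -0.132 millionths (SE 0.506), with a camera adjusted p of 0.776 for the list. The LTI30 and COR15A probes had mean signals of 5.66 and 5.63, under the array lower quartile of 5.67. In the auxin list 4 of 6 measured genes were higher and 2 lower (camera adjusted p = 0.81), with LBD29 at 0.198 millionths (SE 0.133), GH3.1 at -0.649 (SE 1.30), WES1 at -0.135 (SE 0.449) and LBD16 at 0.0913 (SE 0.336). The jasmonate list rested on the thionin gene THI2.1 at -3.26 millionths (SE 0.769) and the defensin gene PDF1.2 at -0.178 (SE 0.601), with a camera adjusted p of 0.417. Both probes were under that quartile as well, with mean signals of 5.55 for THI2.1 and 5.41 for PDF1.2. Whether probes this dim report expression was not tested. The root hair expansin genes EXPA7 and EXPA18 differed by -27.3 (SE 20.8) and -2.12 millionths (SE 5.12), with a camera adjusted p of 0.578. Without single arrays EXPA7 ran from -47.7 to -16.3 millionths. As markers of leaf tissue, LHCB4.1 differed by 0.28 millionths (SE 0.187) and RCA by -0.0573 (SE 0.148), with a camera adjusted p of 0.776. Centring turned the signs of COR47, WES1, PDF1.2 and RCA. The other 13 measured lists of 1 or 2 genes had camera adjusted p from 0.417 to 0.991. Across all 25 measured lists, 0 members passed over all probes by limma. The rank product, with the false calls noted above and its leaning to probes with a wide spread, called APS4, AT3G13610 and MT1C higher and EXPA7 lower. For EXPA7 the values of the 2 groups overlapped. Adjusted over the list alone, by limma, THI2.1, MT1C and the lignin gene HCT passed, and for MT1C and HCT that adjustment is over 1 gene.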

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

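The rescaling of each probe, the limit to lists of 3 or more genes, and every setting of the added lists were chosen after seeing the data. The count of called probes, 0 by limma, stayed at 0 without any single array, with median-centred arrays, trended or robust variance, array weights, Welch's test and the 1.5-fold limit, which no difference could reach. It was 4 among probes above the median signal and 5 above the upper quartile, where fewer probes were tested, and 4 at an adjusted p under 0.10, all lower. With the replicate number as a block it was 1, lower. Same-numbered arrays deviated from their group means with correlations of -0.0188, -0.0181 and 0.103. Differently numbered arrays were not compared in this way, so these values do not decide whether the numbers pair the arrays. Quantile normalization gave 27 calls, 12 higher and 15 lower, but left only 2688 probes with any difference, because the ranks of the other probes were the same on every array. The rank product called 418 and rescaling 337 (104 higher, 233 lower). Of these, 319 were shared. Simulated false calls make both counts uncertain.

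The count of fixed lists past the threshold was 0 in every setting except rescaling, which gave 1, the list with MT1C alone. Of the named genes 2 passed among probes above the median signal and 12 after rescaling, against 0 by limma on the deposited scale. The ribosomal protein list had a median t from -3.24 to -2.53 without single arrays. Under quantile normalization 15 members still varied, with a median t of -1.07 and a camera adjusted p of 0.607.

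Signs turned only for named genes with differences below their errors or close to them (all in millionths). Centring arrays on their medians added 0.598 to every difference, the gap between the group means of the array medians, and this alone turned 8 genes. They became 0.39 for BGLU28, 0.259 for AT1G04770, 0.458 for bZIP19, 0.0178 for BHLH101, 0.42 for PDF1.2, 0.466 for COR47, 0.463 for WES1 and 0.541 for RCA. Under quantile normalization a probe keeps a difference only where its rank changes between arrays, and it then takes the value set for the new rank. There the differences became 1.57 for GSTU15 and 1.51 for bZIP19. Without single arrays the values ran from -11.4 to 0.599 for APS3, -0.0688 to 0.633 for COR15A, -0.555 to 0.137 for COR47, -5.75 to 3.13 for EXPA18, -1.81 to 0.152 for GH3.1, -0.168 to 0.177 for GR1, -0.114 to 0.418 for LBD16, -0.573 to 0.421 for PDF1.2, -0.142 to 0.559 for PYE, -0.135 to 0.0127 for RCA, -0.422 to 0.236 for WES1 and -0.351 to 0.0482 for bZIP19. Leaving out 1 array turned or moved by more than 1.5 times 24 of the 51 named genes, the above among them. The others ran from -1.18 to -0.546 for SIR, -0.331 to -0.129 for BGLU28, -0.521 to -0.0455 for AT1G04770, 1.09 to 3.46 for GSTU20, 0.183 to 0.558 for GSTU25, -8.65 to -1.88 for GSTU15, 0.312 to 1.50 for GSTU18, -1.59 to -0.267 for ZIP6, -0.874 to -0.0342 for BHLH101, 0.0495 to 0.861 for LTI30, -47.7 to -16.3 for EXPA7 and 0.153 to 0.387 for LHCB4.1. In all, 34 of 502 values of named genes turned sign.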

Other observations

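The tests of the spread, of the members seen first and of the counts after rescaling were chosen after the results were seen, and all lists in this part were drawn up after seeing the data. The cytosolic chaperonin (CCT) genes, whose products fold actin and tubulin, were lower in all 8 measured members (median t -2.79, camera adjusted p = 2.54e-06). The adjusted p was 0.092 with an estimated correlation and 0.144 by fry, and none of the members still varied under quantile normalization. AT5G16070 differed by -39.2 millionths (SE 11.5) and AT1G24510 by -82.6 (SE 26.2). Without the members seen first, 6 genes had a median t of -2.64. Genes of leucine breakdown in mitochondria were higher in 8 of 9 members (median t 1.93, camera adjusted p = 0.0361), with MCCA at 71.6 millionths (SE 22.6) and ETFALPHA at 0.696 (SE 0.29) having the smallest unadjusted p. That call was lost with an estimated correlation (adjusted p = 0.416), with fry (adjusted p = 0.552), with centring (adjusted p = 0.101), with quantile normalization (3 members varying, adjusted p = 0.837) and without control replicate 1 (adjusted p = 0.147), control replicate 3 (adjusted p = 0.113), foliar GSH replicate 2 (adjusted p = 0.116) or foliar GSH replicate 3 (adjusted p = 0.0852). Without the genes seen first, 6 members had a camera p of 0.13.

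After rescaling, the higher genes with the smallest p included AT1G07040, AT4G30450, AT3G15450, MT1C, RD2 and ALDH7B4. On the deposited scale AT1G07040 differed by 1296 millionths (SE 195) and AT4G30450 by 1480 millionths (SE 397), with limma adjusted p of 0.373 and 0.593. AT4G36500 was called as well, with a limma adjusted p of 2.25e-07 after rescaling, although its groups overlapped. On the deposited scale it differed by 751 millionths (SE 544, limma adjusted p = 0.926). Of 106 lower genes called after rescaling on probes with 1 gene, 58 encoded cytosolic ribosomal proteins. The lists of mitochondria-encoded genes and of expansins with xyloglucan endotransglucosylases had camera adjusted p of 0.732 each, and the 4 measured sugar starvation markers 0.236. Quantile normalization left 1 of the 15 mitochondria-encoded genes varying and gave that list a median t of -25.8 and a camera adjusted p of 1.34e-04, which rests on that gene alone.

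The compressed spread may come from a summary that scales the deviations of each probe by its own spread. A scaling by range cubed times SD predicts a slope of 3 for log SD on the log of the range-to-SD ratio when noise is normal, and the slope was 1.67 (SE 0.108). Simulated with that scaling, the slope was 2.91 for normal noise and 2.94 with treatment shifts that separate the groups at 11.5% of probes, so shifts of that size do not account for the gap. It was -1.06 for uniform noise and 5.27 for noise with heavy tails. Since the shape of the noise is unknown, the slope does not decide the form of the scaling, which stays open, and the 337 calls after rescaling remain a hypothesis.

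A lower group of ribosomal protein genes may reflect the treatment, brightness, or the way in which the list was found. Lists matched on mean signal argue against brightness, since the median t of 10000 such lists centred on -0.0465 and was -0.679 at the lowest. The -3.11 of the ribosomal list itself is not a fair comparison, because low values led to its choice. Without the 25 members already noticed for their low values, the other 108 had a median t of -2.69. Their camera p was 5.77e-05 with an estimated correlation, so the low values were not confined to the members seen first. These 108 genes belong to the same family and were measured on the same arrays. They may vary together with the members seen first, so this test cannot decide whether the choice of the family explains the shift. Signal shared between similar family members was not tested and stays open. So do the brushing of the leaves, which the untreated controls lacked, and any unrecorded difference in growth or handling between the groups. As a further hypothesis, a sugar starvation programme was tested on 10 starvation and leucine breakdown genes without those seen first, with a median t of 1.14 and a camera p of 0.0184, but 0.0696 with an estimated correlation, so it stays open.

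Plastid-encoded genes had a camera adjusted p of 0.425, with 39 of 67 higher, among them atpB at 359 millionths (SE 120) and atpE at 132 (SE 27.1). Among the 28 lower were ndhF at -0.514 (SE 0.155) and psbN at -4.70 (SE 1.70), each with all GSH arrays below all controls. Leaf tissue in the GSH samples would also raise nuclear photosynthesis genes, whose median t was 0.21 with a camera p of 0.244, which could go either way.

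Exchanging arrays between the groups gives 10 splits, too few for a share under 0.05. The median t of the ribosomal protein list had a size of 3.11 in the real split and at most 1.01 in any other, so 1 split reached it. The list was drawn up after the lowest genes of the real split were seen, which favoured that split. This comparison therefore decides nothing about the list. Rank product calls were 418 against at most 298, and calls after rescaling 337 against at most 157, each reached by 1 split. At an unadjusted limma p under 0.05 the real split gave 1535 probes. Control replicates 1 and 3 grouped with foliar GSH replicate 3 gave more, 1719. The counts of limma calls and of fixed lists past the threshold were 0 in all 10 splits.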
